A study of Mus musculus with 2 samples.

How the data were processed

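H3K9ac ChIP-seq of newborn (postnatal day 0) mouse stomach was analysed from 4 deposited peak lists: 1 for each of 2 replicates, 1 called on both replicates together (pooled) and 1 of replicated peaks. Per the labels, each replicate was a separate biosample of tissue pooled over animals of both sexes, with the same donor label, and library fragments were in the size range 300 to 500. The labels do not say whether the pools shared litters. Both replicates formed 1 group, and no input or control library was analysed here. Coordinates are in build mm10, per the labels, and the ends of all peaks on the chromosomes lay within the chromosome lengths of the reference used.

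Per the file descriptions deposited with the samples, the lists are in narrowPeak format. Replicate 1's list was derived from its alignments and 2 further files whose role is not stated, replicate 2's from its alignments and 1 of those files, the pooled list from both alignments and both files, and the replicated list from the other 3 lists. The aligner, the peak caller and its threshold are not given in the sources used here. Each peak carries a fold enrichment, a ratio to the background that the authors' caller used for that list, as deposited. Each also carries a −log10 p and a −log10 q, as deposited, against the same background. The lowest deposited −log10 p was 2.02, 2.04 and 2.05 in the replicate 1, replicate 2 and pooled lists. Since each list has its own background and depth, these values were ranked or filtered only within a list. Numbers of peaks past a value are set side by side for different lists only as a description. The alignments, read numbers and signal tracks were not analysed here, so the depth per sample is unknown. Precision is given as 95% Wilson intervals of shares, which cover counting error only.

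Genes came from the GENCODE annotation of the same assembly (release M21), with 21938 protein-coding genes on 21 chromosomes and 93513 start sites; 6 replicated peaks on other sequences were left out of gene counts. A promoter peak overlapped 1 kb either side of a start site of any transcript of the gene. Peaks were called shared when their overlap reached 50% of either peak. Random placements (100) kept each peak's chromosome and width and avoided assembly gaps of at least 1000 bases; they were drawn by code written for this purpose in place of the bedtools shuffle first planned. A distal peak lay over 2.5 kb from every annotated start site and was given to the nearest start site of a protein-coding gene. Breadth was the number of bases covered by replicated peaks within 5 kb of the start sites of a gene.

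Gene lists (31), tests and alternatives were fixed before the data were examined. The lists covered gastric cell types, other organs, signalling pathways, imprinted and cell cycle genes, and families by symbol. Members whose symbol was not annotated (Cblif, Loricrin, Foxf1a, Hbb-b1 and G6pc1, synonyms of other members or absent) were left out. Some genes were in more than 1 list, such as Ptch1 in both the gut mesenchyme and the hedgehog list. Promoter peaks of a list were compared with all other protein-coding genes by two-sided Fisher's exact tests. Distal peaks and promoter folds were compared with 10000 random lists of the same size, matched in 10 bins on the length of sequence nearest to each gene or on the CpG observed/expected ratio within 500 bases of the start of the gene, also two-sided. Replicates were compared within lists by exact McNemar tests at equal numbers of strongest peaks. Each family of tests was adjusted by the Benjamini-Hochberg method over its lists, and calls were made at an adjusted p under 0.05. The smallest p that 10000 random lists can give is 0.0002 before adjustment.

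The genes named were the 10 of largest promoter fold, the 10 of most covered bases, up to 4 members per list of largest fold and up to 4 without a promoter peak in the order of the list, the nearest genes of the 10 strongest distal peaks, the Hox genes, and the 5 genes of largest fold with a strong promoter peak in 1 replicate and none in the other, each way. Of these only some are printed, and genes outside the rule are marked as named by values seen afterwards.

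Alternatives were a −log10 q of at least 2, a −log10 p of at least 5, overlap of 1 base or of 50% of both peaks, the pooled list, each replicate's own list in place of the replicated list, promoter windows of 500 bases and 2 kb, 1 start site per gene, other distances and no matching. A −log10 p of at least 10 was added after seeing the data, as were the counts of transcription factor families among the broadest genes with 1 window per gene, without Hox genes and without the 20 broadest genes.

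Each test was tested on simulated data over the 21938 genes in 10 rounds. Fisher's exact test found 58 of 60 planted lists and called 2 of 240 unchanged ones. Simulated promoter peaks were drawn without regard to promoter CpG content. False calls that CpG content can cause in the data were therefore not measured. The random lists matched on CpG found 58 of 60 and called 10 of 240. The distal test found 30 of 30 and called 0 of 270, the fold rank test found 26 of 30 and called 2 of 268, and the McNemar test found 10 of 10 and called 0 of 300. The difference planted for the McNemar test lay in the 81 ribosomal protein genes and was larger than any list showed in the data. Its 10 of 10 therefore says nothing on power at the few differing genes found there. Simulated distal counts scattered only by counting error around a mean set by the length of sequence nearest to each gene. Real counts were less even, with 38 peaks nearest to Gse1. Simulated folds were drawn without regard to CpG content. The rates of the distal and fold rank tests therefore need not hold in the data. All 6 checks of the overlap, distance and placement code, on up to 5000 intervals with known answers, were met. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.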

Results

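Acetylation of lysine 9 of histone H3 (H3K9ac), a histone mark found at active promoters and enhancers, was mapped by chromatin immunoprecipitation and sequencing (ChIP-seq) in the stomach of newborn mice of both sexes on the day of birth (postnatal day 0). The design held 1 group with 2 biological replicates, each made from tissue pooled over several animals, 15 mice in replicate 1 and a number not stated in replicate 2. The question was where in the genome of this tissue the mark lies, so there was no comparison between conditions. Peaks had been called in each replicate alone, 79587 in replicate 1 and 28768 in replicate 2. A further 40216 peaks had been called on both replicates together (the pooled list), and 30703 of these formed a list of replicated peaks. The replicated peaks had a median width of 583 bases and covered 24.8 Mb, or 0.911% of the genome (build mm10). Read numbers were not analysed here, so the depth behind each list is unknown, and all intervals cover counting error only.

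Most of replicate 2's peaks were shared with replicate 1, and most of replicate 1's were not shared with replicate 2. Of replicate 2's peaks, 86.7% (95% Wilson interval 86.3 to 87.1) were shared with replicate 1, meaning that the overlap reached 50% of either peak. Of replicate 1's peaks, 26.8% (26.4 to 27.1) were shared with replicate 2. In 100 random placements of the other replicate's peaks, the shares averaged 2.63% and 0.96% and never came near these values (permutation p = 0.0099 for each, one-sided, the smallest that 100 placements can give). The placements ignored that the mark lies mostly at promoters, so this p does not measure how alike the 2 replicates are. The share depended on the number of peaks: with the 28768 strongest peaks of each replicate by the caller's p, 65.3% of replicate 1's and 78.8% of replicate 2's were shared. In replicate 1, 60.5% of the peaks had a −log10 p below 5, against 35.8% in replicate 2. Among the 21228 replicated peaks on the chromosomes that shared at least 1 base with peaks of both replicates, the ranks of the 2 enrichment values were correlated across regions (Spearman's rho = 0.878). Regions are not independent replicates, so no p is given. Over the peaks far from start sites the rho was 0.549 (2866 regions).

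**Figure D1:**
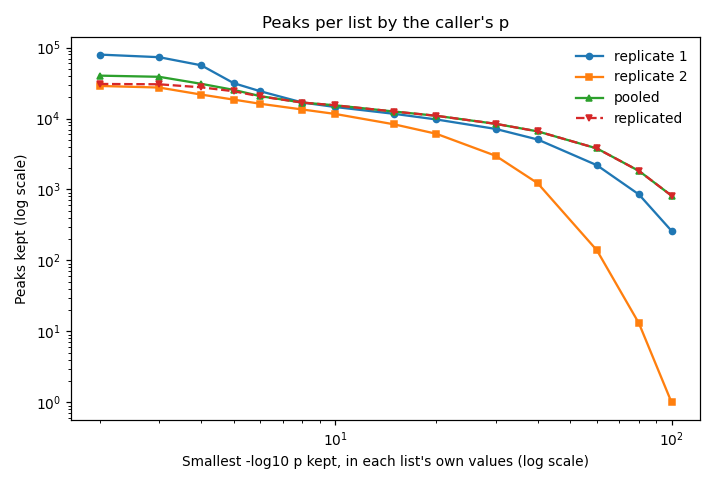
Number of peaks kept (vertical, log scale) at rising minimum values of each list's own −log10 p (horizontal, log scale) for the 4 lists. Replicate 1 has 79587 peaks against 40216 in the pooled list at the left end, and 14543 against 15362 at a −log10 p of at least 10; the p of different lists are not on 1 scale.

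Every replicated peak had the same ends as a pooled peak. All 21088 pooled peaks that both replicates overlapped were in the replicated list, which made up 68.7% of it. The other 9615 replicated peaks were not overlapped by both replicates at this rule, and had a median −log10 p of 4.45 against 21.5 for the rest. The files used here do not state by which rule those were admitted.

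Replicated H3K9ac peaks lay mostly at promoters of protein-coding genes. A peak counted as a promoter peak when it came within 1 kb of an annotated transcription start site, also one inside a gene. This held for 19557 peaks, or 63.7% (63.2 to 64.2), against a mean of 5.7% in 100 random placements of the same peaks (highest 6.01%). A further 4.27% lay at start sites of other transcripts, 21.7% in gene bodies and 10.4% between genes, the last below the random 48.5%. Promoter peaks were wider and stronger than peaks between genes, with median widths of 862 and 358 bases and median fold enrichments of 7.91 and 3.57. The fold enrichment and −log10 p of a peak are the authors' values and were used only to describe, rank or filter peaks within 1 list. Of 21938 protein-coding genes, 13777 (62.8%, 62.2 to 63.4) had a replicated promoter peak. The number was 14732 with replicate 1's own list and 13201 with replicate 2's. The promoter share of the peaks moved more, to 34.5% with replicate 1's list and 72.3% with replicate 2's.

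Rbm39, which encodes a splicing factor, had the promoter of largest fold enrichment, 44.4 (chromosome 2, 156178748 to 156180205, a promoter peak of the gene ENSMUSG00000027620.16). Clk1, a kinase of splicing factors, had 38.5 (chromosome 1, 58422863 to 58424302), Srsf6, a splicing factor of the SR family, had 37 (chromosome 2, 162930488 to 162932524), and Sfpq, another splicing factor, had 36.0 (chromosome 4, 127021254 to 127023648). The other members of the first 10 were Bicral (37.7), Rbbp6 (37.6), the 14-3-3 protein gene Ywhaz (36.1), the RNA cap methyltransferase gene Pcif1 (35.9), the translation initiation factor gene Eif4a2 (35.9) and the chromatin protein gene Hmgb2 (35.7). All 10 also had promoter peaks in both replicates' own lists, with folds from 34.2 to 47.4 in replicate 1 and from 22.7 to 29.2 in replicate 2. A different set came first by breadth, counted as bases covered by replicated peaks within 5 kb of any start site of the gene. Rara, the retinoic acid receptor alpha gene, had 16943 bases, Hoxb3 had 16805, the nuclear receptor gene Nr2f2 had 15653, Bcl9l, a cofactor of beta-catenin, had 14313 and the homeobox gene Meis1 had 14161. Plec (13892), 2010111I01Rik (12895), Zmynd8 (12732), Dab2ip (12446) and Lsp1 (12333) completed the first 10. Across the 13777 genes with a promoter peak, fold and breadth were correlated in rank (Spearman's rho = 0.521), and 48 genes were among the 500 highest of both, against 18.1 by chance. Broad coverage also depended on how many start sites a gene has, since the windows of each were joined.

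Genes of the gut wall's mesenchyme and muscle nearly all carried promoter H3K9ac, and genes of several differentiated cell types of the stomach mostly did not. The tissue was stomach with its cell types mixed, and their shares were not measured. A missing peak therefore does not show that the mark is absent from a cell type that makes up little of the tissue. Of 23 gut mesenchyme genes, 22 had a promoter peak (95.7%, 79 to 99.2; adjusted exact p = 0.000884), led by Zeb1 with a fold of 18.9, Meis1 with 18.6, Meis2 with 18.1 and the hedgehog receptor gene Ptch1 with 17.8. The member without one was Nkx2-3. Against random lists matched on promoter CpG content, which averaged 20.1 of 23, this call did not hold (adjusted permutation p = 0.43). Of 19 smooth muscle genes, 18 had one (adjusted exact p = 0.00645), among them Srf, a transcription factor of contractile genes, with a fold of 29.3, Tpm1 with 18.2, Myl9 with 14.6 and Tpm2 with 12.5. Kcnmb1 had none in the replicated list, but had one in replicate 1's own list (3.14). Of 18 fibroblast matrix genes, 17 had a replicated promoter peak (adjusted exact p = 0.00931), including the collagen genes Col5a1 (14.4) and Col1a1 (12.7), Fn1 (12.6) and Fbn1 (11.8). Postn had none there, but had one in the pooled list. With 1 start site per gene the fibroblast matrix call did not hold (15 of 18, adjusted exact p = 0.0672). Of 19 gastric epithelial transcription factors, 16 had a replicated promoter peak (84.2%, 62.4 to 94.5). This did not pass the threshold (adjusted exact p = 0.073), but did so in the pooled list with 17 (adjusted exact p = 0.0363), in replicate 1's list alone with 18 (adjusted exact p = 0.0153), in replicate 2's alone with 16 (adjusted exact p = 0.047), with a 2 kb window (adjusted exact p = 0.024) and with 1 start site per gene (adjusted exact p = 0.0448). It did not at a −log10 q of at least 2, at a −log10 p of at least 5, with a 500 base window or against random lists matched on CpG (adjusted permutation p = 0.0744). The highest were Klf5 with 20.2, Foxa3 with 15.3 (a peak shared with the promoter of Sympk), Foxa1 with 13.7 and Sox2 with 12. Nkx6-3, Foxq1 and Onecut2 had none in the replicated list. Replicate 1's own list had one at Nkx6-3 (3.45) and at Onecut2 (2.82), and the pooled list had one at Nkx6-3.

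Markers of mature gastric secretory cells gave mixed values. The list for parietal cells, which secrete acid, had promoter peaks at 7 of 11 genes (adjusted exact p = 1), including Slc4a2 (11, shared with Cdk5), Car2 (9.79), Kcnj15 (5.16) and Kcnq1 (4.87). Neither gene of the proton pump, Atp4a and Atp4b, had one in the replicated list, nor did Slc26a7 and Hrh2, but replicate 1's own list had one at Atp4a (3.08) and at Hrh2 (2.82). The list for chief, pit and neck cells had them at 6 of 16 genes (37.5%, adjusted exact p = 0.0788), among them Agr2 (6.05), Ctse (4.87), Tff1 (4.0) and Psca (4.0). Pgc, Gif, Muc5ac and Muc6 had none in the replicated list, but replicate 1's own list had one at Pgc (3.77). The chief, pit and neck list fell below other genes in replicate 2's list alone, with 5 of 16 (adjusted exact p = 0.0323), and also at a −log10 p of at least 5 (adjusted exact p = 0.025), with windows of 500 bases (0.0233) and 2 kb (0.0485) and with 1 start site per gene (0.0143). It was not called below in replicate 1's own list (8 of 16), in the pooled list or at a −log10 q of at least 2. Random lists matched on CpG averaged 4.1 of 16, fewer than the 6 found (adjusted permutation p = 0.45). Gastric endocrine genes were below other genes with 2 of 18 (11.1%, 3.1 to 32.8; adjusted exact p = 3.82e-05). Replicate 1's own list had 5 of 18. The 2 in the replicated list were Slc18a1 (15.2, a peak shared with the promoter of Atp6v1b2) and Slc18a2 (4.72), while the hormone genes Gast, Ghrl and Sst and the histamine enzyme gene Hdc had none. Genes of the squamous epithelium of the forestomach had peaks at 12 of 22 members (adjusted exact p = 0.544), including Perp (13.4), Krt10 (7.19), Krt1 (6.71) and Pkp1 (6.61). The peaks of Krt10 and Krt1, and that of Ctse above, lay inside the gene and away from its outermost start. For Krt1, on the minus strand of chromosome 15, the peak ended at 101846592 and the gene starts at 101850794. These peaks counted through start sites of other transcripts.

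Other cell types of the stomach wall differed. Endothelial genes had promoter peaks at 15 of 19 members (adjusted exact p = 0.187), with Egfl7 at 8.05, Kdr at 7.33, Eng at 6.05 and Cldn5 at 4.87. Erythroid genes had them at 6 of 12 (adjusted exact p = 0.422), with Klf1 at 10.1 and Nfe2 at 7.48 and none at Hba-a1, Hbb-bs, Gata1 or Alas2. The globin genes have near-identical copies, where reads can be lost in alignment. Immune genes were below other genes with 3 of 18 (adjusted exact p = 0.00028), namely Ikzf1 (4.43), Spi1 (3.57) and Coro1a (3.03), but not below random lists matched on CpG (adjusted permutation p = 0.45). The count was 7 of 18 in replicate 1's own list and 2 in replicate 2's. Genes of the enteric nervous system were below with 7 of 21 (adjusted exact p = 0.0167), with Erbb3 at 12.1, Hand2 at 11.4, Ednrb at 7.48 and Elavl4 at 4.72. There was none in the replicated list at Phox2b, Phox2a, Sox10 and Elavl3. The call for the enteric nervous system did not hold in the pooled list (13 of 21, adjusted exact p = 0.85), in replicate 1's list alone (13 of 21, adjusted exact p = 0.678), in replicate 2's alone (8 of 21, adjusted exact p = 0.0562) or with a 2 kb window (9 of 21, adjusted exact p = 0.08). The pooled list and replicate 1's own list had a peak at Phox2a and at Sox10 (folds of 3.77 and 3.14 in replicate 1).

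Genes of other organs, set beside these as a background, were mostly without promoter H3K9ac. Intestinal epithelium had promoter peaks at 3 of 14 genes (adjusted exact p = 0.00669), namely Satb2 (7.77), Hnf4g (4.29) and Vil1 (3.57), and none in the replicated list at the intestinal regulators Cdx1 and Cdx2. Liver had 2 of 15 (adjusted exact p = 0.00033), pancreas 1 of 12 (adjusted exact p = 0.000384), heart and skeletal muscle 2 of 15 (adjusted exact p = 0.00033), brain 4 of 14 (adjusted exact p = 0.0167), lung 2 of 10 (adjusted exact p = 0.0121) and germ cells 1 of 13 (adjusted exact p = 0.000231). Alb, Ptf1a, Myh6, Foxg1, Sftpc and Ddx4 were among the members without a replicated promoter peak. Replicate 1's own list had one at Cdx2 (2.82), Myh6 (4.08) and Sftpc (4.08). With replicate 1's own longer list, 3 of these lists were no longer below other genes, heart and skeletal muscle with 8 of 15 (adjusted exact p = 0.343), brain with 6 of 14 (adjusted exact p = 0.112) and lung with 5 of 10 (adjusted exact p = 0.373). Lung was not below with a 2 kb window either (3 of 10, adjusted exact p = 0.0537). Counts in replicate 1's and replicate 2's own lists also moved where the call held, to 5 and 3 of 14 for intestine, 1 and 1 of 15 for liver, 4 and 0 of 12 for pancreas and 2 and 1 of 13 for germ cells, and brain had 1 of 14 in replicate 2's. Against random lists matched on CpG, 5 of the 7 organ lists were not below, namely intestine (adjusted permutation p = 0.366), liver (0.187), pancreas (0.0744), heart and skeletal muscle (0.277) and lung (0.457). Of 1093 olfactory receptor genes, 2 had a promoter peak (0.183%, 0.0502 to 0.665), and of 327 vomeronasal receptor genes, 1 did (0.306%, adjusted exact p = 5.07e-139), through a peak that Vmn1r4 shared with Nt5c3. Olfactory receptor genes had 8 in replicate 1's own list and 1 in replicate 2's.

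Signalling, growth and housekeeping groups were above other genes. All 12 Wnt target genes (adjusted exact p = 0.00931) had a promoter peak, led by Axin2 (19.9), Znrf3 (15.3), Lgr4 (15.2) and Myc (12.8), as did all 19 cell cycle genes (adjusted exact p = 0.000429), with Mki67 at 13.1 and Cdk1 at 12. Of 14 hedgehog pathway genes, 13 had one (adjusted exact p = 0.0305), with the transducer Smo at 27.3, Gas1 at 18.6 and Cdon at 17.9, and the ligand gene Dhh had none. Of 14 imprinted genes, 13 had one (adjusted exact p = 0.0305), with Grb10 at 15.0 and Igf2r at 14.3, and Ndn had none. The imprinted call did not hold in either replicate's own list (replicate 1, 13 of 14, adjusted exact p = 0.0671; replicate 2, 12 of 14, adjusted exact p = 0.0689) or with 1 start site per gene (10 of 14, adjusted exact p = 0.453), nor did the hedgehog call in replicate 1's (13 of 14, adjusted exact p = 0.0671). Ribosomal protein genes had peaks at 78 of 81 (adjusted exact p = 1.38e-11), proteasome genes at 37 of 39 (adjusted exact p = 3.61e-05) and respiratory complex I genes at 37 of 37 (adjusted exact p = 3.13e-07). The ribosomal exceptions were Rpl10l, Rpl39l and Rpl3l, and the proteasome exceptions were Psmb11 and Psma8, all of them tissue-restricted paralogs. Replicate 1's own list had a peak at Rpl3l (4.08) and at Psmb11 (4.39). In all, 11 of the 31 lists were above and 13 below other genes (two-sided Fisher's exact test, Benjamini-Hochberg over the 31 lists, adjusted p under 0.05). Genes were treated as independent and are not replicates. Against 10000 random lists matched on promoter CpG content, the hedgehog (adjusted permutation p = 1), Wnt (0.738), cell cycle (0.45), proteasome (0.0744) and complex I (0.0945) calls did not hold. By this test 4 of the 11 stayed above (fibroblast matrix, smooth muscle, imprinted and ribosomal protein genes) and 7 of the 13 stayed below (gastric endocrine, enteric nervous system, brain, germ cell, olfactory and vomeronasal receptor genes and Hox paralogs 10 to 13). CpG content was taken at 1 start per gene, while peaks counted at any start site, so the matching was incomplete for genes with several. Of the 4 lists that stayed above, fibroblast matrix and imprinted genes lost their call by Fisher's exact test with 1 start site per gene.

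**Figure D2:**
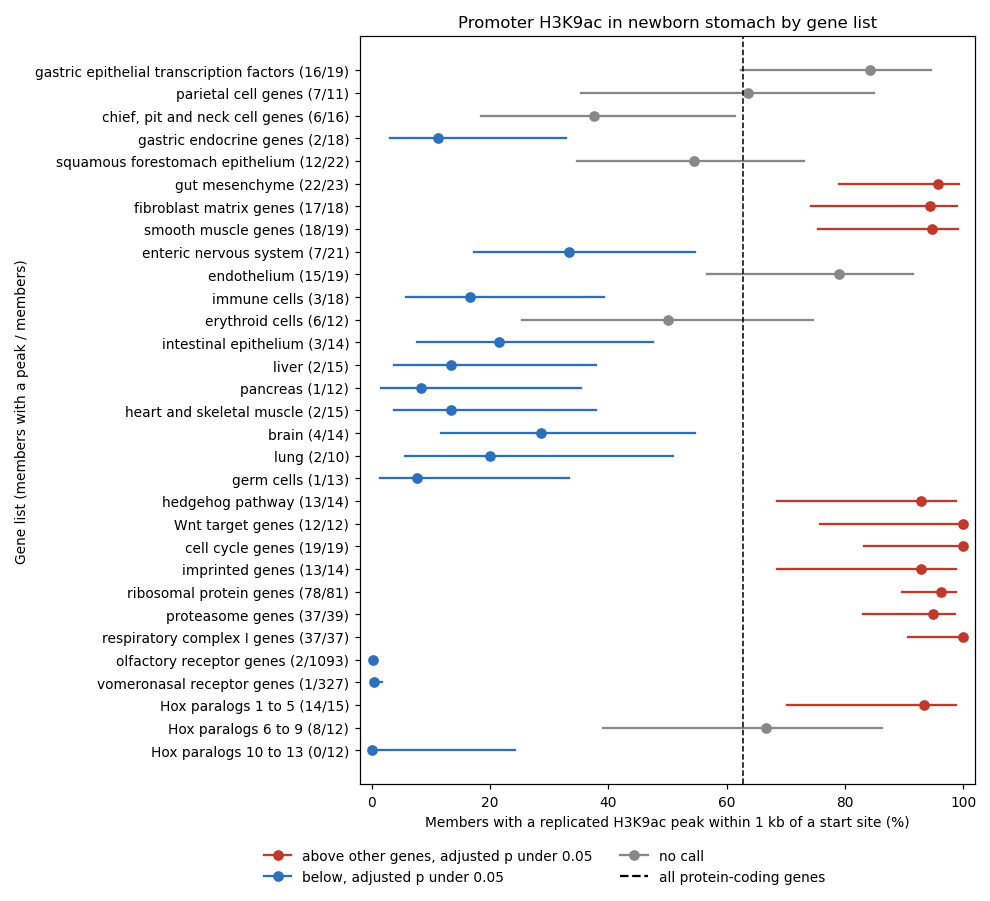
Percent of members with a replicated H3K9ac peak within 1 kb of a start site (horizontal) for the 31 gene lists (vertical). Points are shares, bars their 95% Wilson intervals and the dashed line the 62.8% of all protein-coding genes; gut mesenchyme, fibroblast matrix and smooth muscle genes lie at 94.4% to 95.7%, gastric endocrine genes at 11.1%.

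Along the Hox clusters, which encode the homeobox factors of body axis position, promoter H3K9ac ended between paralog groups 8 and 9. Of the 15 genes of paralogs 1 to 5, 14 had a replicated promoter peak (adjusted exact p = 0.0199), with Hoxa5 at a fold of 17.6 (chromosome 6, 52202296 to 52204419), Hoxa4 at 16, Hoxa2 at 15.5 and Hoxb2 at 14. Hoxd1 had none there, but had one in replicate 1's own list (3.45) and in the pooled list. All 8 genes of paralogs 6, 7 and 8 had a replicated promoter peak, such as Hoxb6 at 8.2, Hoxa7 and Hoxb7 at 8.05, Hoxc6 at 7.61 and Hoxd8 at 5.16. None of the 16 genes of paralogs 9 to 13 had one. For paralogs 10 to 13 alone the count was 0 of 12 (Wilson upper bound 24.2%; adjusted exact p = 3.61e-05), and paralogs 6 to 9 together had 8 of 12 (adjusted exact p = 1). Hoxd3 and Hoxd4 shared 1 peak (fold 4.15), and Hoxb1 had the lowest fold of these genes (2.7) with no promoter peak in replicate 2's own list. With a −log10 q of at least 2, Hoxb1 lost its peak and the list of paralogs 1 to 5 no longer passed the threshold, with 13 of 15 (adjusted exact p = 0.0761). The call was also lost at a −log10 p of at least 5 (adjusted exact p = 0.0719), with 1 start site per gene (adjusted exact p = 0.148) and against random lists matched on CpG, which averaged 11.8 of 15 (adjusted permutation p = 0.276).

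**Figure D3:**
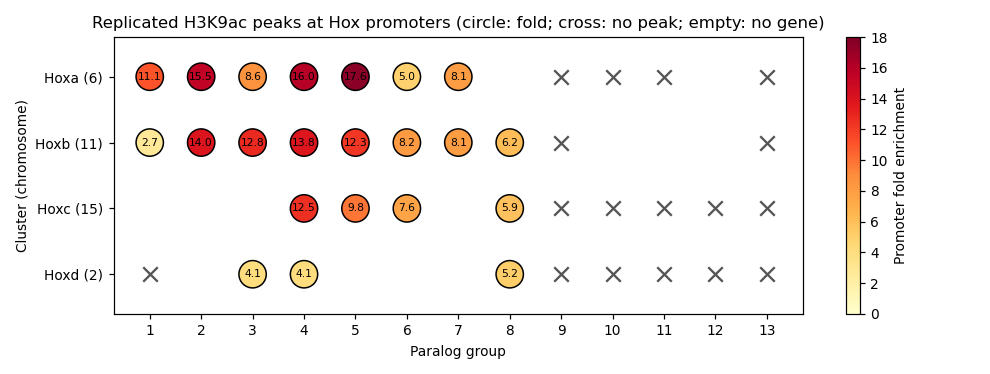
Promoter fold enrichment in the replicated list (colour and number in each circle) for the Hox genes by cluster (vertical, chromosome in brackets) and paralog group (horizontal), with crosses for genes without a promoter peak and empty places where the cluster has no such gene. Circles end at paralog group 8, and the highest fold is 17.6 at Hoxa5.

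Among genes with a promoter peak, ribosomal protein and proteasome genes had the highest promoter folds of the lists. The median over 78 ribosomal protein genes was 17.6 (interquartile range 13.7 to 22.2), against 13.3 in random lists drawn from genes with a promoter peak and matched on CpG (adjusted permutation p = 0.0038), with Rpl17 at 33.2 and Rpl19 at 32.5. The median over 37 proteasome genes was 15.6 (11.3 to 19.1) against 11.7 (adjusted permutation p = 0.0209), with Psmd6 at 26.6, but in replicate 2's list alone this call did not hold (adjusted permutation p = 0.0591). Endothelial genes had a median of 4.38 (3.56 to 4.8) against 9.21 (adjusted permutation p = 0.019), which did not hold in replicate 1's list alone (adjusted permutation p = 0.0526). In replicate 2's list alone, squamous forestomach and gut mesenchyme genes were also below (adjusted permutation p = 0.018 and 0.0236). The 7 enteric nervous system genes with a peak had a median of 4.72 against 10.8 (adjusted permutation p = 0.019). Ranked by covered bases in place of fold, a choice also made in advance, the order changed. Gut mesenchyme genes then stood above their random lists with a median of 4480 covered bases against 1624 (adjusted permutation p = 0.000633), as did smooth muscle genes with 4575 against 1375, gastric epithelial transcription factors with 3254 against 1460, Hox paralogs 1 to 5 with 5912 against 1528, Hox paralogs 6 to 9 with 4688 against 1520, hedgehog pathway genes with 2763 against 1592 (adjusted permutation p = 0.0119) and ribosomal protein genes with 2217 against 1732. Proteasome genes did not (1337 against 1608, adjusted permutation p = 0.158), and the endothelial and enteric lists were no longer called below. The endothelial median stayed lower than in random lists (924 against 1434, adjusted permutation p = 0.0912). The enteric median was higher (2319 against 1487, adjusted permutation p = 0.141). Windows of neighbouring Hox genes overlap, so the same bases count for several members and the Hox values are not independent. The random lists were matched neither on such clustering nor on the number of start sites per gene.

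Peaks far from promoters gathered near genes of the gut mesenchyme and of smooth muscle. Of the replicated peaks, 7076 (23.1%) lay over 2.5 kb from every annotated start site. The 23 gut mesenchyme genes were the nearest protein-coding genes of 56 of them, against a mean of 12.9 in random lists matched on the length of sequence nearest to each gene (4.34 times as many, adjusted permutation p = 0.0186). The 19 smooth muscle genes were nearest to 33 against 6.37 (5.18 times, adjusted permutation p = 0.0279). In replicate 1's list alone the ratios were lower, 2.55 for gut mesenchyme (204 against 79.9) and 3.35 for smooth muscle (116 against 34.6), with both calls kept. By values seen afterwards, Foxf1 had 8 such peaks, Meis1, Meis2, Ptch1 and the myosin light chain kinase gene Mylk had 7 each, and Csrp1 had 6. Neither call held when only peaks over 5 kb from a start site were counted (41 against 10.3, adjusted permutation p = 0.0579, and 18 against 4.54, adjusted permutation p = 0.171). Fibroblast matrix genes had 35 peaks against 9.23 (adjusted permutation p = 0.0703), gastric epithelial transcription factors 26 against 8.79 (adjusted permutation p = 0.149) and Hox paralogs 1 to 5 had 12 against 2.26 (adjusted permutation p = 0.0703), none past the threshold. In this order, their ratios of 3.79, 2.96 and 5.3 were 2.01, 2.21 and 2.6 in replicate 1's list alone. In replicate 2's list alone they were 3.86, 4.02 and 7.61. From 1 kb, fibroblast matrix genes with 52 (adjusted permutation p = 0.00868) and Hox paralogs 1 to 5 with 20 (adjusted permutation p = 0.0217) were above. Olfactory receptor genes had 10 against 191.2 and vomeronasal receptor genes 3 against 109 (adjusted permutation p = 0.0031 for each). The random lists were not matched on promoter H3K9ac. Hedgehog (2.62 times), imprinted (2.59), Wnt (2.46), cell cycle (2.21) and ribosomal protein genes (2.07) also exceeded their random means, without a call. Proteasome (1.14) and complex I genes (0.816) lay near theirs. How much of the gathering goes with promoter H3K9ac alone was not tested.

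The 10 distal peaks of largest fold lay between 5.36 and 184 kb from the nearest start site of a protein-coding gene. The first had a fold of 26.2 (chromosome 8, 69716086 to 69716946, between genes, 5.36 kb from a start site of Zfp869). The next were between genes on chromosome 2 (18766343 to 18767724, fold 22.4, 67.3 kb from Spag6), on chromosome 12 (8640765 to 8641675, fold 19.8, 32.5 kb from Pum2) and on chromosome 18 (75342249 to 75343626, fold 19.5, 23.9 kb from Smad7, an inhibitor of TGF-beta signalling). One in an intron of Prdm2 had a fold of 19.5 (chromosome 4, 143160970 to 143162216), and one in an intron of the non-coding gene Lncppara had 18.5 (chromosome 15, 85669476 to 85673336, nearest to Ppara). The remaining peaks of the first 10 were nearest to Nufip1 (17.8), Foxn2 (17.6), Arhgap32 (17.5) and Chd2 (17.0). All 10 were overlapped by peaks of both replicates.

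Promoter peaks lay at largely the same genes in the 2 tissue pools. At 28768 strongest peaks from each replicate, 13463 genes had a promoter peak in replicate 1 and 13201 in replicate 2, and 12894 had one in both. The 22 gut mesenchyme, 18 smooth muscle, 17 fibroblast matrix and 16 gastric transcription factor genes with a peak were the same number in both replicates, with no member in 1 replicate alone. None of the 31 lists differed by the exact McNemar test (two-sided, 0 lists at an unadjusted p under 0.05). The smallest p was 0.25, for heart and skeletal muscle genes, where 3 genes had a peak in replicate 1 alone. At most 5 genes of a list differed, for which no p below 0.0625 is possible, so the test could not have called any list and says nothing on whether the make-up of the pools differed. By fold in the list of the replicate itself, genes among the strongest of replicate 1 without any promoter peak in replicate 2 numbered 569, led by A830031A19Rik (11, shared with Bcl11a), Zscan10 (9.42), Ushbp1 (9.18), Ccdc8 (9.1) and Dclk1 (8.16). Replicate 2 had 49 such genes against the longer list of replicate 1, led by AC140267.1 (14.8, shared with Mief1), Tmem91 (5.14), Samd9l (4.52), Mucl3 (4.52) and Sdhaf1 (4.48). The replicated peaks of A830031A19Rik and AC140267.1 lay beside the start of the gene and did not cover it. Whether such genes were counted only through a shift of a peak's end across the 1 kb window was not tested. These comparisons are between 2 libraries and not between conditions.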

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

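Among the alternatives here, only the threshold of −log10 p of at least 10 was chosen after seeing the data. The number of genes with a promoter peak stayed between 12959 and 14732 under all its alternatives, no call of the main analysis reversed, though by promoter level gut mesenchyme genes, without a call there, were below in replicate 2's list (adjusted p = 0.0236 by permutation) and above by covered bases (adjusted p = 0.000633 by permutation). None of the 31 lists was called different between replicates under any of 5 alternatives (smallest adjusted p = 0.323, with whole lists, where 3 lists had an unadjusted p under 0.05 by the exact test). At most 7 genes of a list differed in these alternatives, for which the exact test gives no p below 0.0156. They could therefore hardly have called a list over 31, and do not show that the replicates are alike. Values that moved by more than their counting interval, or counts by over 1.5 times, were as follows. Replicate 1 kept 42772 peaks at a −log10 q of at least 2. At a −log10 p of at least 5 replicate 1 kept 31475, replicate 2 18466 and the pooled list 25317, and at 10 they kept 14543, 11608 and 15362, with 15360 in the replicated list. The shared share of replicate 1 and replicate 2 was 28.6% and 90.7% at 1 base, 20.4% and 56.5% at 50% of both peaks, 40.3% and 93.8% with the q threshold, 50.2% and 95.9% with the p threshold, and 65.3% and 78.8% with equal numbers. At 50% of both peaks, 51.6% of the replicated list was overlapped by both. The promoter share of peaks was 68.3% and 72.9% with the q and p thresholds, 54.7% in the pooled list, 58.6% and 70.1% with windows of 500 bases and 2 kb, 51.1% with 1 start site per gene, and 34.5% to 72.3% with 1 replicate's list. Matching on CpG left 4 lists above and 7 below. For distal peaks, 0 lists were above from 5 kb, 4 from 1 kb and 4 without matching. By promoter level, 7 lists were above and 0 below with covered bases, 6 below without matching, and 1 to 2 above and 3 to 4 below with 1 replicate's list. The rho was 0.894 with −log10 p, 0.549 at distal peaks and 0.87 with the q threshold. Hox paralogs 1 to 5 also lost their call with 1 start site per gene, as did fibroblast matrix and imprinted genes, and the lung and enteric lists with the 2 kb window. Of the 130 named genes with a promoter peak, 5 lost it at the q threshold, 8 in replicate 2's list and 1 in replicate 1's. Of the 98 without, 24 had one in replicate 1's list and 9 in the pooled list. Apart from the thresholds and windows, which remove or add peaks by construction, the cause was not tested. Unknown depth limits how far the absence of a peak can be read.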

Other observations

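Genes chosen after their values were seen stood out for the number of distal peaks nearest to them. Gse1 had 38, the corepressor genes Ncor2 and Ski had 24 and 22, Irf2bp2 had 20, Cstad and Sh3pxd2a had 19 each, the non-muscle myosin gene Myh9 had 18, and Zfp36l1 and Smad7 had 17 each. All of these also had a promoter peak, with folds from 7.77 at Cstad to 30.6 at Irf2bp2. The 7076 distal peaks were nearest to 3607 protein-coding genes.

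Start sites of non-coding genes also carried the mark, in part through promoters of nearby protein-coding genes. Over all annotated genes of each kind, a replicated peak lay within 1 kb of a start site of 12.9% of long intergenic non-coding RNA genes, 33% of antisense genes, 13.1% of microRNA genes and 0.996% of processed pseudogenes. Of 5350 long intergenic non-coding RNA genes with no protein-coding start site within 2 kb of theirs, 412 (7.7%) had a replicated peak within 1 kb that was not itself a promoter peak of a protein-coding gene. On the same terms the share was 8.23% of 1652 antisense genes, 3.94% of 1725 microRNA genes and 0.679% of 9577 processed pseudogenes. Among the strongest, also named by values seen afterwards, were Mir17hg, the host gene of a microRNA cluster, with a fold of 19.8 (chromosome 14, 115040267 to 115042701), and Snhg12, a host gene of small nucleolar RNAs, with 17.3 (chromosome 4, 132308600 to 132310057).

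The 3 patterns below were noticed in these data and all their tests were added afterwards; those at a −log10 p of at least 10 and of promoter CpG were chosen after their result was seen, and the background explanation was narrowed to even spread after its value was seen, with bounds set before. No biological explanation was tested because the design has 1 group. Replicate 1's list was 1.98 times as long as the pooled list that includes its reads. At a −log10 p of at least 10 the ratio was 0.947, but pooling reads raises the p of shared regions, so this ratio cannot tell whether peaks near the caller's threshold are the cause. The 42303 replicate 1 peaks that shared no base with a pooled peak had a median −log10 p of 4.02 and lay within 2.5 kb of a start site 2.13 times as often as random placements (31.5% against 14.8%), which argues against background spread evenly over the genome as their whole source. One region split into several peaks is argued against as the whole source, since 18.5% of them lay within 1 kb of a pooled peak (3.88% in random placements), but may account for part. Background that is itself denser in open chromatin, and the unstated role of the further files behind the list, stay open.

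Families of developmental transcription factors (Hox, Fox, Sox, Gata, Tbx, Nkx, Pitx, Meis, Irx, Klf, Pax, sine oculis-related, Lhx, Dlx and Msx genes) held 32 of the 500 broadest genes (odds ratio 10.1, 6.47 to 15.5) and 3 of the 500 of largest fold (0.673, 0.136 to 2.03). The families were chosen after the broadest genes were seen, so the odds ratio is partly fixed by the choice and is no evidence of enrichment (7.78, 4.74 to 12.4, without the 20 broadest genes, which were those seen). The odds ratio was 10.6 (6.8 to 16.2) with 1 window per gene and 6.5 (3.69 to 10.9) without Hox genes. It thus did not rest only on the number of annotated start sites per gene or on neighbouring genes in the Hox clusters. Without those 20 genes the odds ratios in these settings were 8.21 (5.03 to 13) and 4.39 (2.22 to 8.01), a check added after the other values. Since the families were still those chosen from these data, no conclusion on a cause is drawn. What sets these genes apart stays open.

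The end of promoter acetylation between Hox paralogs 8 and 9 was weighed against 2 technical explanations. Of depth and the caller's threshold, only the threshold could be weighed. A list kept too short is argued against, since replicate 1's list, the longest, held a promoter peak at 1 of the 16 genes of paralogs 9 to 13 (Hoxb9, fold 2.82). The pooled list also held 1 (Hoxb13, fold 3.13). All lists come from the same 2 libraries, whose depth is unknown, so acetylation too weak for that depth stays open. Promoter CpG content is argued against as well, since random lists matched on it averaged 89.9% of members with a promoter peak, with a lowest value of 50% among 10000 lists. How well reads align in these clusters was not tested and stays open.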
